A study of Mus musculus with 6 samples.

How the data were processed

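Gene expression was measured on microarrays in mouse embryonic fibroblasts (MEF), primary cells grown out of E14.5 embryos. There were 3 wild type samples and 3 samples carrying FOG-2 Rb-, a knock-in form of the GATA co-factor FOG-2 (gene Zfpm2) that, by the study's title, cannot bind the retinoblastoma protein pRb. Per the labels' protocols, growing cells were trypsinized, total RNA was extracted with Trizol and a purification kit, and biotin-labelled single-stranded DNA was made with an Affymetrix whole-transcript kit. The submitters' processing notes name RMA and Partek. Their versions, the probe definition and the genome build are not given in the sources used here, so no coordinates are printed.

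The authors deposited a table of log2 expression values with 23748 rows and 6 samples, with 1 Entrez gene per row. RMA, named in the submitters' processing notes, is a method that corrects the background, normalizes between arrays and summarises over probes. The scanner files were not used here, so background, saturation and scan batches were not examined. The authors also deposited a table of their own comparison, which gives a p-value, a ratio of mutant over wild type and a signed fold change for each gene. The log2 of that ratio differed from the difference of group means in the log2 table by at most 7.18e-06, which fixes the scale and the direction. The log10 of the deposited p-value differed from that of an ordinary 2-group ANOVA of the same values by at most 2.34e-06. The log2 table served as the main table because the other one holds no values per sample. Median log2 expression was 5.73, 5.68 and 5.65 in wild type replicates 1 to 3 and 5.68, 5.68 and 5.69 in FOG-2 Rb- replicates 1 to 3.

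The platform annotation gave 1 gene symbol for 23111 rows, several for 0 and none for 637. Rows without a symbol there were tested and counted but are unnamed here and belong to no gene list. Symbols in the lists that the annotation did not hold were matched through a unique synonym in a RefSeq gene table (assembly GRCm38.p6), which otherwise served for gene order only. For Gpi1 and Eno1, both current symbols of other rows, this led to Pigq and Eno1b, which belong to other genes; the glycolysis list is given with and without them.

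Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the only term, all 6 arrays), with Benjamini-Hochberg adjustment over the 23748 rows and a threshold of 0.05. Every adjusted p for a gene is from this fit. Fold changes are FOG-2 Rb- over wild type, or the inverse for lower genes, from differences of mean log2 values. Errors are SDs over 3 arrays or limma's standard errors (SE) of log2 fold changes. The number of arrays limits the precision, and fold changes of genes near the background of the array are understated.

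The comparison, its test, most alternatives and 37 gene lists with 764 different genes were fixed before the data were examined. The way list genes were matched to rows was not: it was settled after a first exploratory fit, in which rows were named through their Entrez IDs and synonyms were not used. That earlier matching was kept as an added alternative, as was the matching without Pigq and Eno1b. Of the 764 genes, 719 were matched to a row, 717 of them without these 2. The 36 lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 36 lists. Camera with a correlation estimated from the data and the rotation test fry were run beside it. The preset correlation treats the genes of a list as nearly independent.

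The rule for named genes takes the 12 highest and the 12 lowest fold changes among genes past the threshold whose arrays did not overlap between genotypes, leaving out predicted and unnamed gene models, small RNAs and odorant or pheromone receptors. It also takes up to 4 members per list, those past the threshold with the largest change or else the member with the smallest p, and, whatever their values, the FOG, GATA and retinoblastoma family genes, Pparg, Ucp1, Prdm16, the Y-linked genes and Xist.

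The fit was tested on simulated data with the means and within-genotype SDs of all 23748 rows, in which 4 sets of 50 genes were changed. It recovered 14% of the genes changed by 0.3 on the log2 scale, 62% of those changed by 0.5, 92% of those changed by 1 and 98% of those changed by 2. Of its 138 calls, 5 were false. The data gave 4281 calls. With far fewer changed genes the adjustment is stricter, so these shares may understate the recovery of small changes in the data. Camera called a list shifted by 0.3 and 0 of 100 unshifted lists. The simulated genes varied independently of each other, so this says nothing about false calls for lists whose genes vary together. In the data the estimated correlation reached 0.218, in the extracellular matrix list.

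The alternatives left out each array in turn, added the replicate number as a block, changed the variance prior, the centring, the normalization, the array weights, the threshold or the filter on dim rows, or used an ordinary ANOVA.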

Results

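RNA of growing fibroblasts, collected before any differentiation, was measured in 3 wild type and 3 FOG-2 Rb- samples. The comparison asks how gene expression differs in cells whose FOG-2 cannot bind pRb. The labels number the samples of each genotype as experiments 1 to 3 and do not say whether these were separate embryos or cultures, so p-values measure the spread between these samples, which may be technical. The titles carry the number 18 in each wild type sample and 27 in each FOG-2 Rb- sample, with no stated meaning, so genotype and whatever this number marks cannot be told apart.

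FOG-2 Rb- fibroblasts had lower Zfpm2, lower Gata2 and higher Gata4 and Gata6. Zfpm2, the targeted gene, measured 9.76, 9.65 and 9.64 on the log2 scale in wild type replicates 1 to 3 and 9.40, 9.39 and 9.40 in FOG-2 Rb- replicates 1 to 3. Its mean fell from 9.68 ± 0.07 to 9.40 ± 0.01 (SD, n = 3 each), a log2 fold change of -0.29 (SE 0.05, adjusted p = 0.00913). Its level does not check the labels, since a changed binding site need not alter it. Among the GATA factors, the transcription factors that FOG proteins bind, Gata4 rose 2.14-fold (log2 1.10, SE 0.10, adjusted p = 0.000687) and Gata6 rose 1.84-fold (0.88, SE 0.06, adjusted p = 0.000131). Gata2, a factor that restrains adipocyte formation, fell 2.03-fold (log2 fold change -1.02, SE 0.06, adjusted p = 7.75e-05). Zfpm1, which encodes FOG-1, rose 1.37-fold. Gata3 had a log2 fold change of 0.17 (adjusted p = 0.068), Gata1 of 0.04 (adjusted p = 0.745) and Gata5 of -0.00 (adjusted p = 0.997). Of the 8 FOG and GATA genes, 3 rose, 2 fell and 3 did not pass; adjusted over the list alone, 4 rose and 2 fell. The list as a set did not pass camera (adjusted p = 0.323). Rb1, which encodes pRb, had a log2 fold change of 0.12 (SE 0.04, adjusted p = 0.122) and Rbl2 of -0.12 (adjusted p = 0.143), while Rbl1, which encodes p107, fell 1.37-fold (adjusted p = 0.00195).

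**Figure D1:**
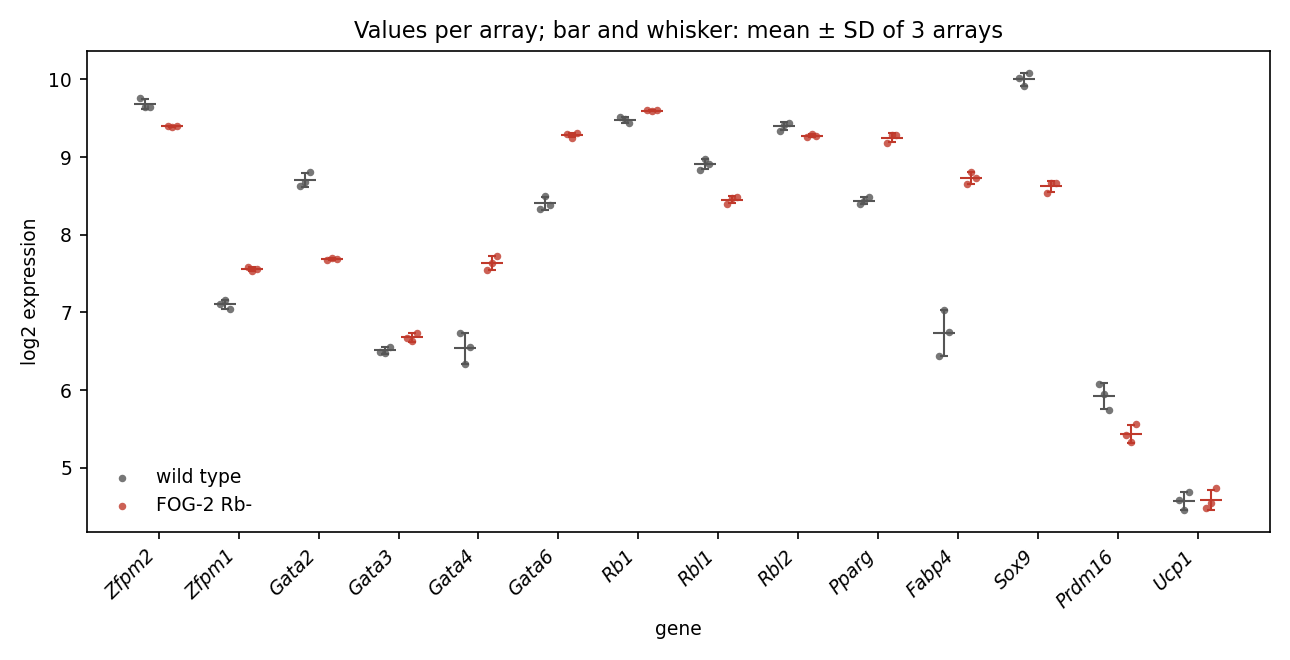
Log2 expression (vertical axis) of 14 genes in each array, wild type in grey and FOG-2 Rb- in red, with a bar and whisker for the mean ± SD of 3 arrays. Gata2 and Sox9 were lower and Gata4, Gata6, Pparg and Fabp4 higher in each FOG-2 Rb- array than in any wild type array, and Ucp1 overlapped.

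Across the genome, 4281 of 23748 genes (18%) differed between the genotypes, 2241 higher and 2040 lower in FOG-2 Rb-. Most changes were small: 3425 of the 4281 were under 1.5-fold, and the median absolute log2 fold change of the changed genes was 0.35. By 2-fold or more, 183 genes rose and 111 fell, 294 in all, and beyond 4-fold 35 rose and 15 fell. Values of the genotypes did not overlap for 8461 genes (35.6%), where chance gives 10%. Correlations across genes were 0.997 to 0.998 within a genotype and 0.990 to 0.991 between genotypes, and the first principal component held 67.0% of the variance. Without FOG-2 Rb- replicate 3, the count of changed genes was 2805. The authors' deposited table holds 6700 genes at an unadjusted p under 0.05 and 3553 after Benjamini-Hochberg adjustment of its p-values.

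Serpinb6b, a serine protease inhibitor, rose 12.8-fold (log2 3.68, SE 0.05, adjusted p = 4.23e-07). Scel, which encodes the cornified envelope protein sciellin, rose 12.2-fold, Upk1b, a uroplakin of the urothelium, 9.68-fold, and Sprr1a, another cornified envelope gene, 8.90-fold. Sytl5 rose 9.38-fold, Crybg1 8.65-fold, the zinc-sensing receptor gene Gpr39 8.33-fold, the transferrin gene Trf 7.52-fold and the prostacyclin synthase gene Ptgis 7.32-fold. The protocadherin gene Pcdhgb5 rose 7.14-fold, Aldh1a1, which encodes a retinaldehyde dehydrogenase, 6.43-fold, and Clca3a1 6.38-fold. Among named genes, Lrrn3 had the largest fall, 7.26-fold (log2 fold change -2.86, SE 0.06, adjusted p = 1.91e-06). The urea transporter gene Slc14a1 fell 7.21-fold, Itm2a 6.34-fold, the imprinted gene Mest 5.43-fold and Eng, which encodes the TGF beta co-receptor endoglin, 5.33-fold. Pde9a fell 5.23-fold, Cdh13 5.19-fold, Elobl 5.09-fold, the Wnt agonist gene Rspo2, among the 40 named genes nearest to Zfpm2 in gene order, 4.99-fold and the interleukin 1 receptor antagonist gene Il1rn 4.47-fold. The T-box factor gene Tbx20 fell 4.19-fold and Dkk2, a Wnt modulator, 4.16-fold.

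**Figure D2:**
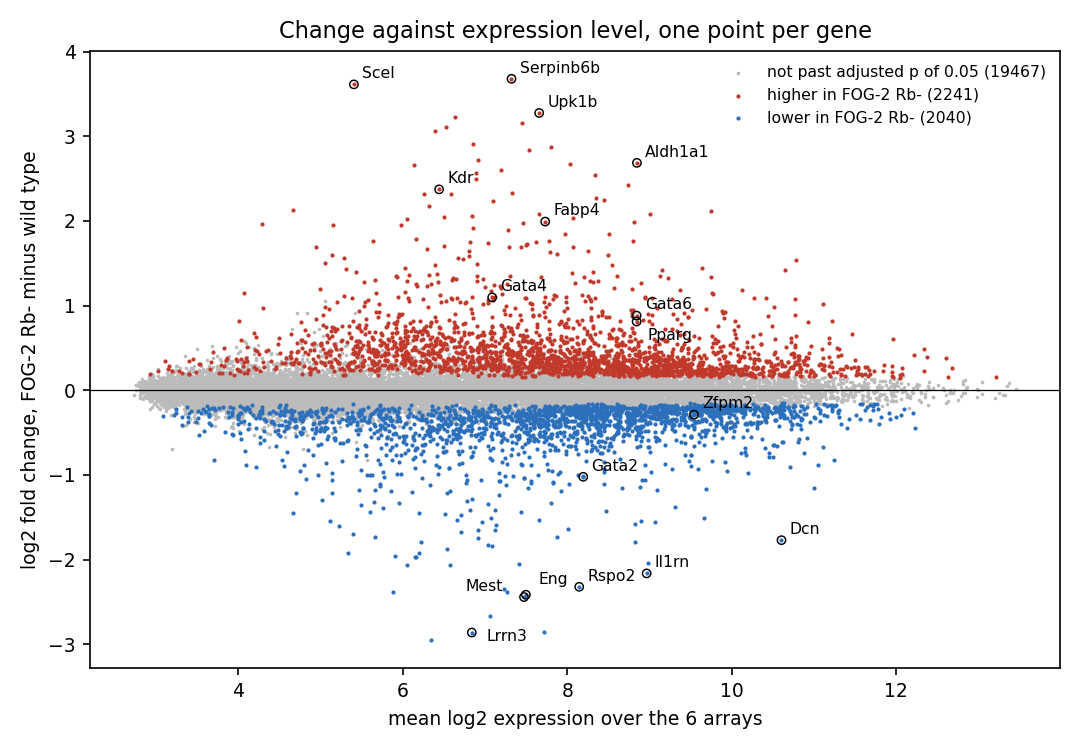
Log2 fold change of FOG-2 Rb- minus wild type (vertical axis) against mean log2 expression over the 6 arrays (horizontal axis), 1 point per gene, with 2241 higher genes in red, 2040 lower genes in blue and the others in grey. Labelled genes reached from a log2 fold change of -2.86 (Lrrn3) to 3.68 (Serpinb6b).

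Many genes of DNA replication and mitosis fell in FOG-2 Rb- cells. Of 36 measured E2F targets of DNA replication, 24 fell and 1 rose (25 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.31. The licensing factor gene Cdt1 fell 1.80-fold, the helicase genes Mcm5 and Mcm6 1.69-fold and 1.48-fold, and Gins3 1.69-fold. The single rise was lost without wild type replicate 2 or FOG-2 Rb- replicate 1, 2 or 3 (0 higher). Of 34 mitotic genes, 19 fell and 0 rose (23 and 0 adjusted over the list alone), with a median of -0.19. Mybl2, a cell cycle transcription factor gene, fell 1.53-fold, the kinase gene Nek2 1.45-fold, the spindle checkpoint gene Mad2l1 1.38-fold and the spindle motor gene Kif11 1.38-fold. Of 17 genes of the retinoblastoma and E2F proteins, 8 fell and 0 rose (9 and 0 adjusted over the list alone); E2f8 fell 1.64-fold, E2f7 1.46-fold, Lin9 1.41-fold and E2f4 1.40-fold. Camera gave adjusted p = 2.78e-10 for the replication list, 9.05e-10 for the mitotic list and 0.00122 for the retinoblastoma and E2F list; with an estimated correlation, adjusted p = 0.0965, 0.0965 and 0.232.

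Some histone genes fell as well. Of 17 measured, 6 fell and 0 rose (9 and 0 adjusted over the list alone), with a median log2 fold change of -0.28; H2ac4 fell 1.37-fold, H1f2 1.30-fold, H1f4 1.27-fold and H2bc3 1.26-fold. In camera the list had adjusted p = 0.00834, and adjusted p = 0.484 with an estimated correlation. The 6 falls became 3 without wild type replicate 2, 2 without FOG-2 Rb- replicate 1, 1 without replicate 2 and 0, with 1 rise, without replicate 3. None of these histone genes was found under the Entrez naming of the exploratory fit. Of 19 p53 targets and cell cycle inhibitors, 3 rose and 2 fell (4 and 3 adjusted over the list alone); Cdkn1c rose 1.32-fold and Trp53inp1 fell 1.39-fold. That list did not pass camera (adjusted p = 0.957), and 1 rise was left without wild type replicate 1 or FOG-2 Rb- replicate 1, 2 or 3.

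Pparg and Fabp4 rose, in a list of adipogenic genes that did not pass as a set. Of 19 inhibitors of adipogenesis and preadipocyte genes, 11 fell, 1 rose (Klf2, log2 fold change 0.51) and 7 did not pass. Adjusted over the list alone, 11 fell and 3 rose, and the median log2 fold change was -0.27. Sox9 fell 2.6-fold, Cd34 2.56-fold, Gata2 2.03-fold and the PDGF receptor gene Pdgfra 1.87-fold. The list passed camera with adjusted p = 0.000285, and adjusted p = 0.249 with an estimated correlation. Of 29 adipogenic regulators and adipocyte genes, 7 rose and 5 fell (9 and 7 adjusted over the list alone). Pparg, the nuclear receptor that drives adipocyte formation, rose 1.76-fold (log2 0.81, SE 0.05, adjusted p = 0.000139), and its target Fabp4, a fatty acid binding protein gene, rose 3.98-fold (log2 1.99, SE 0.14, adjusted p = 0.000191). Ebf2 and Retn fell 1.59-fold and 1.56-fold. Among members picked after their values were seen, Cebpd fell (log2 fold change -0.59). Cebpa (0.17), Adipoq (-0.07), Plin1 (0.09) and Cd36 (0.03) did not pass. Of 24 brown and beige adipocyte genes, 1 rose and 4 fell (the same counts adjusted over the list alone). The riser was Pdk4 (2.54-fold), a kinase gene that restrains glucose oxidation, and Ppargc1a fell 1.5-fold. Prdm16 fell 1.40-fold (log2 fold change -0.49, SE 0.10, adjusted p = 0.0158), a call lost without wild type replicate 2 or FOG-2 Rb- replicate 1 or 2. Ucp1, the uncoupling protein gene of brown fat, stayed at log2 4.58 ± 0.12 and 4.59 ± 0.13 (SD, n = 3 each; log2 fold change 0.01, adjusted p = 0.95). Neither the adipogenic list (camera adjusted p = 0.324) nor the brown and beige list (0.323) passed as a set. The 5 falls of the adipogenic list became 3 without any 1 array except FOG-2 Rb- replicate 2, which left 4, and the 4 falls of the brown and beige list became 2 without FOG-2 Rb- replicate 1 or 2.

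Of 20 measured fatty acid oxidation genes, 4 rose, 0 fell and 16 did not pass (5 rose and 0 fell adjusted over the list alone): the very long chain acyl-CoA dehydrogenase gene Acadvl rose 1.5-fold, Etfb 1.34-fold, Acads 1.30-fold and Acaa2 1.24-fold. This list had adjusted p = 0.00834 in camera, and adjusted p = 0.232 with an estimated correlation. Of 32 oxidative phosphorylation genes, 5 rose and 1 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.643). Its 5 rises became 2 without wild type replicate 1 or 2 or FOG-2 Rb- replicate 3, and 3 without any other array. Atp5o rose 1.49-fold and Ndufv2 fell 1.24-fold. Glycolysis (1 higher and 1 lower of 20, camera adjusted p = 0.942) and cholesterol biosynthesis (1 higher and 3 lower of 19, adjusted p = 0.324) did not pass as sets; counts adjusted over the list alone were equal to these. The glycolysis list held Pigq, a gene of GPI anchor synthesis, in place of Gpi1, and Eno1b in place of Eno1, through shared synonyms; without both, 1 of 18 rose and 1 fell (camera adjusted p = 0.957). Within this list the fall of Hk2 (1.18-fold) was lost without wild type replicate 1 or 3 or FOG-2 Rb- replicate 2 or 3, leaving 0. In cholesterol biosynthesis Idi1 fell 1.39-fold, and the rise of Insig1 (1.14-fold) was lost without any 1 of the 6 arrays, leaving 0.

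Of 33 measured positional transcription factors outside the Hox clusters, 16 fell and 6 rose (18 and 6 adjusted over the list alone), with a median log2 fold change of -0.24. The T-box genes Tbx3 and Tbx5 fell 2.99-fold and 2.51-fold, the homeobox gene Alx1 2.50-fold and the paired box gene Pax1 2.15-fold. As a set they had adjusted p = 0.000239 in camera, and adjusted p = 0.0965 with an estimated correlation. Of 20 Hox A and B genes, 6 fell and 0 rose (6 and 1 adjusted over the list alone); Hoxa10 fell 1.47-fold and Hoxa9 1.46-fold. For the set, camera gave adjusted p = 0.0349, which became 0.0904 without wild type replicate 2, 0.0875 without FOG-2 Rb- replicate 1, 0.0617 without replicate 3, 0.141 without dim rows and 0.108 under Entrez naming; adjusted p = 0.249 with an estimated correlation. The 6 falls became 2 without wild type replicate 1 or 2, 3 without wild type replicate 3 or FOG-2 Rb- replicate 1, and 2, with 1 rise, without FOG-2 Rb- replicate 3. Of 18 Hox C and D genes, 4 rose and 0 fell (4 and 1 adjusted over the list alone); Hoxd8 rose 1.68-fold and Hoxc8 1.22-fold, and the list did not pass (camera adjusted p = 0.643). Those 4 rises became 2 without wild type replicate 2 or 3 or any FOG-2 Rb- replicate, with 1 fall without FOG-2 Rb- replicate 3.

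Matrix genes moved both ways. Of 33 extracellular matrix genes, 12 rose and 5 fell (15 and 5 adjusted over the list alone). The proteoglycan genes Dcn and Lum fell 3.41-fold and 2.93-fold and the fibrillin gene Fbn2 2.69-fold, and the microfibril gene Mfap5 rose 1.58-fold. The median log2 fold change was 0.11 and the mean -0.02, so these differ in sign, and camera, which called the list higher, gave adjusted p = 0.0267. The call was lost without wild type replicate 1 (adjusted p = 0.0818), FOG-2 Rb- replicate 2 (0.0658) or replicate 3 (0.053), with centred arrays (0.0507), quantile normalization anew (0.0581) or no dim rows (0.0991); adjusted p = 0.622 with an estimated correlation. Of 16 metalloproteinases and other matrix proteases, 7 rose and 3 fell, also adjusted over the list alone, with a median of 0.19. Adamts9 rose 2.55-fold, Mmp23 1.71-fold and Mmp19 1.45-fold, and the urokinase gene Plau fell 1.58-fold. Camera gave adjusted p = 0.0211, or 0.066 without dim rows, and adjusted p = 0.232 with an estimated correlation; without FOG-2 Rb- replicate 2, 1 gene fell.

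Some genes of the Wnt pathway and of skeletal cells fell. Of 23 Wnt signalling genes, 7 fell, 2 rose and 14 did not pass (7 fell and 3 rose adjusted over the list alone); Rspo2 fell 4.99-fold, Dkk2 4.16-fold, and the secreted modulator genes Dkk3 and Sfrp1 2.00-fold and 1.78-fold. Rspo2 encodes an agonist of the pathway, whereas Sfrp1 encodes an inhibitor. Axin2 and Lef1, targets of the pathway singled out after their values were seen, had log2 fold changes of -0.08 (adjusted p = 0.606) and -0.16 (adjusted p = 0.13). Camera gave adjusted p = 0.0211, or 0.0591 without wild type replicate 1, 0.0991 without dim rows and 0.0657 under Entrez naming; adjusted p = 0.402 with an estimated correlation. Of 18 chondrocyte and osteoblast genes, 6 fell, 0 rose and 12 did not pass, with equal counts adjusted over the list alone; Dlx5 fell 2.62-fold and the cartilage factor gene Sox9 2.6-fold. Camera gave adjusted p = 0.0349, or 0.104 without wild type replicate 1, 0.0596 without wild type replicate 2, where 3 genes fell, 0.0891 without FOG-2 Rb- replicate 2 and 0.07 with quantile normalization anew; adjusted p = 0.402 with an estimated correlation. Of 24 TGF beta and BMP signalling genes, 7 rose and 4 fell (7 and 6 adjusted over the list alone). Bmp4 rose 2.71-fold, while Tgfbi fell 2.25-fold, Bmp2 2.01-fold and Id2 1.79-fold, and the list did not pass (camera adjusted p = 0.525).

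Many mesothelium genes rose. Of the planned cell type lists, that of chondrocytes and osteoblasts passed camera as lower (adjusted p = 0.0349), as given above. The epithelial, endothelial, smooth muscle, cardiac, macrophage, neural, skeletal myogenic and erythroid lists did not pass. None of these had an unadjusted camera p under 0.05, and fry called only the cardiac list among them, as lower (adjusted p = 0.0245). The mesothelium list was drawn up after the largest changes had been seen, without those genes. It still holds 5 genes of the epithelial list, whose counts had been seen. Of its 18 genes, 11 rose and 2 fell, with a median log2 fold change of 0.46, and 9 to 11 rose with 1 array left out. Among them, as examples chosen after their values were seen, Slc9a3r1 rose 2.11-fold and Cldn15 1.90-fold, and Efemp1 fell 1.36-fold. Adjusted over all 42 lists tested, camera gave adjusted p = 0.000165 for this list, and adjusted p = 0.0949 with an estimated correlation. The adjustment does not correct for choosing the theme from these same arrays, so these values are no independent support. Without the 5 genes shared with the epithelial list, 8 of 13 rose and 1 fell. Of 17 epithelial genes, 4 rose and 2 fell, also adjusted over the list alone: the keratin gene Krt18 rose 4.72-fold, Upk3b 2.44-fold and Wt1 2.10-fold, and Msln, a mesothelial surface protein gene, fell 2.35-fold (list adjusted p = 0.643; 1 fall without FOG-2 Rb- replicate 1 or 3). Of 18 endothelial genes, Kdr, a VEGF receptor gene, rose 5.18-fold, Eng fell 5.33-fold and 16 did not pass (adjusted p = 0.896). Of 16 smooth muscle and myofibroblast genes, 6 rose and 4 fell (8 and 4 adjusted over the list alone); Myl9 rose 1.41-fold, and Itga8 and the calponin gene Cnn1 fell 1.79-fold and 1.72-fold (adjusted p = 0.532). Of 16 cardiac genes, Gata4 rose, and Tbx20, Mef2c (2.66-fold) and Tbx5 fell (2 rose and 3 fell adjusted over the list alone; adjusted p = 0.68; 2 rises without wild type replicate 3). Of 19 macrophage and leukocyte genes, 3 rose and 0 fell, with Cd68 1.62-fold higher (adjusted p = 0.68). Of 16 neural and glial genes, 2 rose and 3 fell (3 and 3 adjusted over the list alone); Fabp7 rose 3.87-fold and Stmn2 fell 1.70-fold (adjusted p = 0.643; 1 rise without wild type replicate 1 or 3 or FOG-2 Rb- replicate 2). Of 18 skeletal myogenic genes, Des rose 1.32-fold and Pax3 fell 1.30-fold (adjusted p = 0.905; 0 rises without wild type replicate 2 or 3 or FOG-2 Rb- replicate 2 or 3). Of 9 erythroid genes, Epor rose 1.17-fold, a call left only without wild type replicate 1 (adjusted p = 0.835; 0 rises without each other array). In the endothelial, macrophage, skeletal and erythroid lists the counts adjusted over the list alone were equal to those given.

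Single genes of stress and immune signalling changed strongly in lists that did not pass camera. Of 24 cytokine and chemokine genes, 7 rose and 6 fell (8 and 7 adjusted over the list alone); Il33 rose 6.06-fold and Cxcl12 2.68-fold, and Il1rn fell 4.47-fold and Ccl5 2.67-fold (adjusted p = 0.683). Of the lists here, fry called the cytokine list higher (adjusted p = 0.000781) and the antioxidant (0.00314) and imprinted lists (0.000514) lower. Of 24 interferon response genes, 4 rose and 2 fell (8 and 2 adjusted over the list alone); Ifit1 and Cxcl10 fell 1.89-fold and 1.71-fold (adjusted p = 0.464; 2 rises without FOG-2 Rb- replicate 1). Of 17 antioxidant genes and NRF2 targets, 5 rose and 6 fell (6 and 6 adjusted over the list alone); the metallothionein genes Mt2 and Mt1 fell 2.00-fold and 1.91-fold, Nqo1 fell 1.95-fold and Slc7a11 rose 1.69-fold (adjusted p = 0.962; 3 rises without wild type replicate 1 or 2 or FOG-2 Rb- replicate 1 or 2). Of 18 unfolded protein and amino acid response genes, 3 rose and 1 fell (5 and 2 adjusted over the list alone), with Psat1 1.31-fold lower (adjusted p = 0.554; 1 rise without wild type replicate 2 or any FOG-2 Rb- replicate). Of 18 immediate early and stress genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone); Fosb and Fos rose 1.56-fold and 1.49-fold and Ier3 fell 1.53-fold (adjusted p = 0.942). Of 21 imprinted genes, 4 rose and 7 fell (5 and 7 adjusted over the list alone); Mest fell 5.43-fold, Zim1 2.11-fold, Igf2r 1.85-fold and H19 1.42-fold (adjusted p = 0.325). Across the 3 measured Y-linked genes, Eif2s3y, Kdm5d and Uty, all 6 arrays lay between 3.28 and 3.78 on the log2 scale, Xist lay between 11.69 and 11.75, and Tsix had a log2 fold change of -0.08 (adjusted p = 0.514). None of the 5 passed the gene test, and the Y-linked list gave a camera adjusted p = 0.957. Y-linked genes this low with Xist this high in every array are the pattern of female cells, so the values show no sex difference between the genotypes.

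Of the 36 lists, 12 passed camera at the preset correlation, 3 higher and 9 lower. With an estimated correlation, camera called 0 of the 36, with 6 at an unadjusted p under 0.05. Fatty acid oxidation (-0.0433), positional factors (-0.00966), matrix proteases (-0.00673) and Hox A and B genes (0.00211) had estimated correlations below the preset 0.01. Their calls were lost as well, so a higher correlation alone does not account for the loss. The other lists past camera had estimates above 0.01. With an estimated correlation, camera also judges its statistic on the few residual degrees of freedom of 6 arrays, and at the preset on those of all genes. That setting is therefore stricter by construction. For fatty acid oxidation the unadjusted camera p went from 0.00153 to 0.0259. The 0 of 36 is thus not in itself evidence that list genes vary together. Fry called 19 of the 36. Besides the cardiac, cytokine, antioxidant and imprinted lists, fry called 4 that camera did not: FOG and GATA factors (adjusted p = 0.00823), adipogenic genes (0.0199) and Hox C and D genes (0.0181) higher and cholesterol biosynthesis (0.00314) lower. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes.

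**Figure D3:**
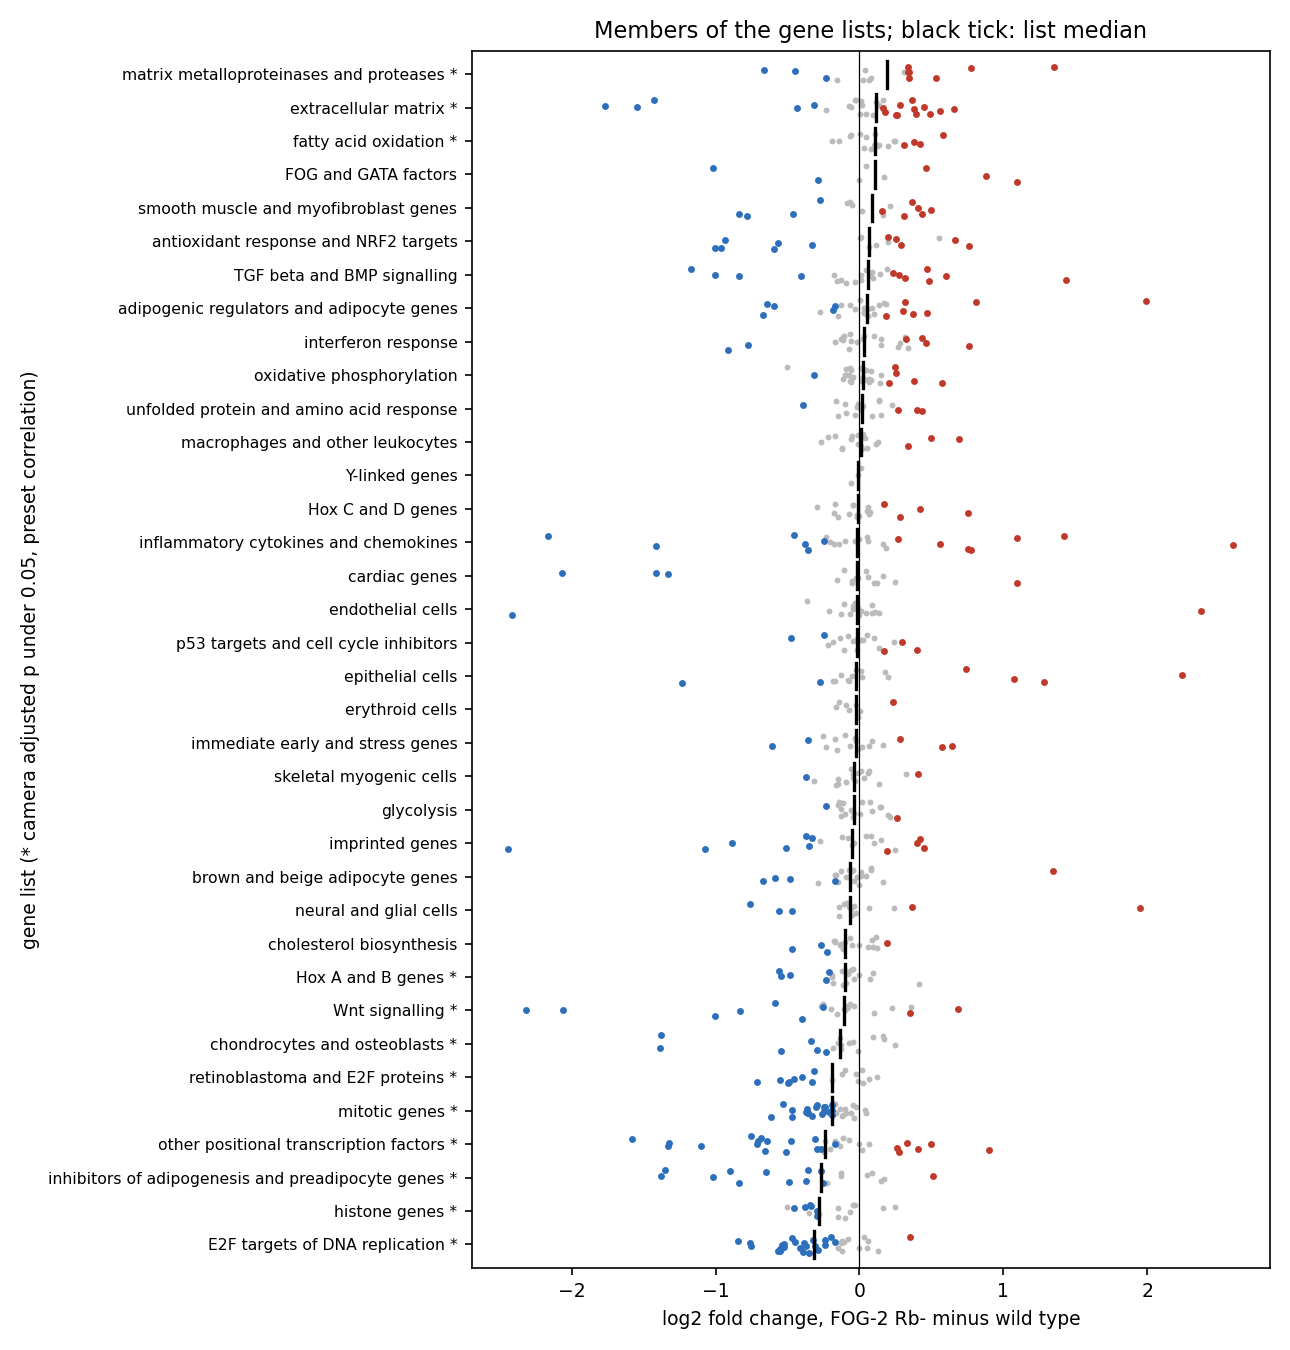
Log2 fold change of FOG-2 Rb- minus wild type (horizontal axis) of each measured member of 36 gene lists (vertical axis), with higher genes in red, lower genes in blue, genes that did not pass in grey, a black tick at each list's median and a star at the 12 lists past camera. The replication list had the lowest median (-0.31) and the matrix protease list the highest (0.19).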

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

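The matching of list genes by Entrez naming and the matching without Pigq and Eno1b were alternatives chosen after seeing the data; the others were planned. All values here concern the comparison of FOG-2 Rb- with wild type. With 1 array left out in turn, 2805 to 3446 genes changed, the lowest without FOG-2 Rb- replicate 3, against 4281 with all 6 arrays; fewer arrays give fewer calls by construction. At an adjusted p under 0.01 the count was 2215, and at 1.5-fold in place of 2-fold 871 genes changed, both by the construction of the threshold. Of the 36 lists, 12 passed camera, 0 passed with an estimated correlation and 19 passed fry, 11 of them called by camera in the same direction; the cause was not tested beyond the tests' own construction, since fry does not compare a list with other genes. Under Entrez naming 9 of 35 lists passed, each of them also called by the main matching. The Wnt list (adjusted p = 0.0657) and the Hox A and B list (0.108) did not pass there, and no histone gene was found, so these 3 calls depend on a matching chosen after a first look at the data. Without Pigq and Eno1b, 12 lists passed, the same ones in the same direction. With the experiment number as a replicate block, 3181 genes changed, 294 by 2-fold or more, and 12 lists passed. The labels do not say that the number marks a shared embryo, batch or day. For that reason the fit without a block was planned before the data were examined. Same-numbered samples had deviations from their group means that correlated at 0.03, 0.02 and 0.00, against -0.03 to 0.02 for different numbers. Of the 6 samples, 3 correlated best with their own number. The fall of Zfpm2 passed in every alternative that was run for it. Over the 14 alternatives run for the other 155 named genes, 27 lost their call in at least 1, and 0 changed direction with a call. No list changed direction with a call, and each of the 12 lists lost its call in at least 1 alternative, the estimated correlation. The deposited ratios hold no values per sample, so the other deposited table could not be run as an alternative, and averaging several rows of a gene was void with 1 row per gene. Camera has no value under robust eBayes or ordinary ANOVA. Signal over background could not be judged without detection values, and genes near the level of the Y-linked ones have little range to fall.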

Other observations

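Several further lists were drawn up only after the genes with the largest changes had been seen, with those genes left out of them; both tests of the neighbouring genes and the tests of the level trend, of the share of cycling cells and of mesothelial cells were also chosen after results bearing on them had been seen. Secreted growth factor genes moved in both directions in FOG-2 Rb- cells. Igf1 was 3.13-fold higher, Vegfc 2.15-fold, Angpt2 2.13-fold and Gas6 1.98-fold higher, and Pdgfd was 1.71-fold and Nrg1 1.48-fold lower, with 10 of 32 rising and 6 falling. Among axon guidance genes, 9 of 33 rose and 7 fell, with Sema6d 2.06-fold higher and Nrp2 2.43-fold, Epha3 2.30-fold and Unc5c 2.27-fold lower. Among insulin-like growth factor binding proteins and related genes, 5 of 11 rose and 3 fell, with Igfbp3 1.68-fold higher and Igfbp5 2.08-fold lower. These genes were picked after their values were seen. Besides the mesothelium list, none of the 5 added lists shifted as a set in camera, with adjusted p = 0.723 for retinoid handling (1 of 17 higher and 3 lower), secreted growth factors, insulin-like growth factor binding proteins and keratinization (3 of 24 higher and 1 lower), and 0.959 for axon guidance.

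The number of changed genes was the first pattern weighed. The 6 samples can be split into 3 and 3 in 10 ways. Of these splits, 1, the real one, gave as many as 4281 genes, 294 genes by 2-fold or more and 12 lists. The highest counts of the other splits were 0, 0 and 4, with 544 to 834 genes at an unadjusted p under 0.05 in limma. Each other split mixes the genotypes, which puts the genotype difference into its spread and lowers its counts. Those counts therefore do not show what chance alone gives, and 10 splits are too few for a share under 0.05. Donor strain DNA carried along with the knock-in would change genes near Zfpm2: of the 40 nearest named genes in gene order, 30% changed (exact 95% interval 16.6% to 46.5%), against a median of 17.5% and a 95th percentile of 32.5% over all windows of 40 genes, so the share decides nothing. Of these 40, 3 changed by 2-fold or more, Rspo2 (log2 fold change -2.32), Angpt1 (-1.88) and Fzd6 (1.84), and 3.00% of windows held as many, but these genes had been seen before that test was set. These 40 held 12 of the 4281 changed genes, so an effect confined to them does not directly account for the count. Donor DNA and other effects local to the locus stay open for the neighbouring genes, and their indirect effects on genes elsewhere were not tested. For the count, a difference between embryos or cultures, as the numbers 18 and 27 in the titles could mark, and the genotype itself stay open.

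The lower replication and mitotic genes were the second pattern. Of 10000 random lists matched on level, 0% had a median as low as the -0.24 observed over both lists, and the lowest was -0.11, which argues against a level-dependent trend left by the normalization. A lower share of cycling cells may account for the falls. It was taken to lower both lists alike, a premise that was not tested. Within the lists the falls were uneven. Of 36 replication genes, 24 fell, 1 rose and 11 did not pass, and of 34 mitotic genes 19 fell and 15 did not pass. Among those that did not pass, picked after their values were seen, log2 fold changes were -0.00 for Rrm2, 0.06 for Tk1 and 0.04 for Ccnb2. The replication median minus the mitotic median was -0.12 (95% bootstrap interval -0.22 to 0.04), which neither reaches nor excludes an equal fall. The bootstrap drew genes as if they were independent, so the comparison does not decide this explanation. A difference in culture density or growth state between the samples, and an effect of the FOG-2 change, stay open.

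The third pattern was the rise of mesothelium and epithelium genes among the largest changes, for which more mesothelial cells in the FOG-2 Rb- cultures are a candidate explanation. In a list of 18 mesothelium genes without those seen first, 11 rose and 2 fell, with a median log2 fold change of 0.46, and 5 of the 18 (Krt19, Krt8, Msln, Upk3b and Wt1) also stand in the epithelial list, whose counts had been seen. Of 5 genes picked as abundant in mesothelium, 4 rose (Upk3b to a mean log2 expression of 7.54, Wt1 7.13, Krt19 5.84 and Lrrn4 4.46), while Msln fell from 7.78 to 6.55. All 5 stand among the 18, so they are no separate evidence. The fall of Msln goes against added mesothelial cells and the other 4 go with them, so mesothelial cells and a change of these genes within the fibroblasts cannot be told apart, and the labels name no sort or gate that would remove such cells.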
